A study of Rattus norvegicus with 6 samples.

How the data were processed

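Gene expression was measured in single cells of the testis of SD rats, a laboratory strain of the brown rat. Tissue came from 3 control animals and from 3 animals that had gone through a stress model in which a frightening sound is played, and each animal gave 1 library. Per the labels' protocols, the tissue was minced and dissociated with enzymes, and libraries were made with the Singleron GEXSCOPE kit, which captures single cells in a microfluidic device, and sequenced on an Illumina NovaSeq. The aligner, the counting tool, the genome build and the filter on cells are not given in the sources used here.

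For each library the authors deposited a table of counts per gene and cell, whose values were whole numbers of at least 0. The sources used here do not say whether a count is a read or a molecule. Values equal to 1 made up 12.4% to 18.4% of the values above 0 in a library, and the median count of a detected gene in a cell was 5 to 13. The intervals below therefore cover counting error only and treat counts as independent, which reads without molecular identifiers are not. The authors also deposited a normalized table per library, in natural log units, and the values show that it was made from the counts as the natural log of 1 plus the count scaled to 10000 per cell, with 0 values that differed by more than 1e-09. The normalized tables entered no test. The deposited cells had been filtered before deposit: no cell had more than 5.00% mitochondrial counts, and the highest number of genes in a cell was 3984, 3996 and 3559 in the control libraries and 3491, 3498 and 3499 in the stressed libraries. The tables list 21170 genes, of which 19988 had a count in at least 1 library and 4941 carry an identifier in place of a symbol. Symbols were used as the tables give them. A reference table of rat genes on assembly GRCr8 was used for names only, so no coordinates are printed.

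Total counts were 94130353, 73650164 and 114984746 in control replicates 1 to 3 and 16756543, 93898869 and 74453303 in stressed replicates 1 to 3, so stressed replicate 1 has the lowest precision. Pairs of libraries of the same group differed far beyond sampling noise, with a chi-square per degree of freedom of 163 to 621. They are thus not copies of each other. That they come from separate animals rests on the labels, which this test cannot check. Each library was counted as a separate replicate. Cells with at least 200 genes and at most 20% mitochondrial counts were kept, which left all 11744 cells. Scrublet, as run in scanpy, called 67 cells doublets, 0.571% of all cells. These were left in, and leaving out the 5% of cells with the highest scores in each library was tried as an alternative.

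Cells were clustered with scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2 in Python 3.11.15, and scanpy 1.11.5 was used for Scrublet only. The clustering used 2000 variable genes, less any mitochondrial genes among them, 30 principal components, 15 neighbours and a Leiden resolution of 1. All libraries were clustered together, with no correction between them. Clusters were named from 12 marker lists. A cluster kept a name only with at least 3 detected markers of that class and without more markers of another class than of its own among its 10 leading genes. Such classes are called "like" the cell type, since no annotation of the authors was used. The classes found were spermatogonia-like, spermatocyte-like, round spermatid-like and elongating spermatid-like cells. No cluster met the rule for Sertoli, Leydig, peritubular myoid, stromal, endothelial, macrophage, or T and natural killer cells, so the tests planned for these classes were not run. A cluster of 297 cells led by Apoe, Fos, Cd74, Selenop and Lyz2 stayed unnamed. Spermatogonia-like cells numbered 20 and were too few to test.

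Cells are not replicates. Counts were summed per library and class where a library had at least 20 cells of the class, and also over all cells of a library. Sums were tested between the groups with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filter filterByExpr and robust estimation, and Benjamini-Hochberg adjustment over the genes tested in a class. A gene was called at an adjusted p under 0.05. CPM values of single genes in the classes are scaled by the TMM factors, and summed CPM values of lists are not. Shares of cells were compared with a 2-sided exact permutation test of the group means, which cannot give a p below 0.1 for 3 against 3 animals. Shares of single libraries carry Wilson 95% intervals. Of 29 fixed gene lists, 28 had at least 5 tested members in a class and were tested with camera in limma 3.58.1, at a preset correlation of 0.01, with adjustment over all 75 tests of a list in a class. Of 671 different genes written into the fixed lists, 57 were not found under that name in the tables used here. The median log2 change over all tested genes lay between -0.03 and 0.00 in the classes and the whole-library sums.

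The tests, the gene lists, the marker lists and the rule for naming genes were fixed before the data were examined. Named genes are, per class, up to 10 genes called in each direction whose groups do not overlap, with the smallest p. Where fewer than 5 passed, the list was filled to 5 per direction by p, and such genes are said not to pass. Identifiers without a symbol were to be counted and not named. The 2 that were called are named all the same, a choice made after their values were seen. For a called gene list, the members with the smallest p are named. Nr3c1, Fkbp5 and Tsc22d3 are given in each class, Sycp3 and Piwil1 in spermatocyte-like cells, and Tnp1, Tnp2, Prm1, Prm2, Akap4 and Acrv1 in the spermatid-like classes. Prm1 was not analysed here.

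The tests were run on simulated counts drawn for the real genes, with 200 genes changed by known folds. At a 4-fold change, edgeR called 37.3% of changed genes in the spermatocyte-like sums, 47.8% in the round spermatid-like sums, 40.3% in the elongating spermatid-like sums and 32.8% in the whole-library sums. At a 2-fold change it called 2.99%, 8.96%, 2.99% and 1.49%, so most changes of that size would be missed. Calls of unchanged genes numbered 2, 5, 3 and 6. A list raised 1.5-fold was called in each of the 3 classes, with 0 other lists called by camera. Genes were drawn independently of each other, without the correlation that members of a list may have in real sums. The simulation therefore cannot show how often camera calls an unchanged list in these data.

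Alternatives planned were DESeq2 1.42.0, RLE scaling in edgeR, no filter on low counts, limma voom with sample weights, the replicate number as a block, leaving out each replicate, a stricter cell filter (500 genes and 10% mitochondrial counts), Leiden resolutions of 0.5 and 2, clusters found within each library, at least 50 cells per library, camera with an estimated correlation and fry. Counting the unnamed cluster as elongating spermatid-like, leaving it out of the whole-library sums, and leaving out control replicate 2 and stressed replicate 1 together were chosen after seeing the data. Of the genes named by the rule, some are not reported here. Figures were drawn with matplotlib 3.10.9.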

Results

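The study asks whether psychological stress disturbs the formation of sperm in the rat testis. Single-cell libraries of 3 control animals and 3 animals exposed to a frightening sound held 2342, 1801 and 2453 cells (control replicates 1 to 3) and 409, 2506 and 2233 cells (stressed replicates 1 to 3). Total counts were 94130353, 73650164 and 114984746 in the controls and 16756543, 93898869 and 74453303 in the stressed animals, in the order of replicates, and the median count per cell from 27987 to 41632. Stressed replicate 1 was the smallest library in both cells and counts.

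Nearly all cells fell in classes of germ cells, the sperm-forming lineage. Over the 6 libraries, 6183 cells were elongating spermatid-like, 3885 round spermatid-like, 1359 spermatocyte-like and 20 spermatogonia-like. Spermatocytes are the cells in meiosis, and round and elongating spermatids are the haploid cells that follow. Elongating spermatid-like cells made up 51.8% ± 3.43 (SD, n = 3) of control cells and 42.1% ± 28.6 (SD, n = 3) of stressed cells, round spermatid-like cells 35.4% ± 8.87 and 28.9% ± 8.13, and spermatocyte-like cells 11.4% ± 7.56 and 10.1% ± 5.70. Spermatogonia-like cells made up 0.190% ± 0.221 and 0.258% ± 0.223. None of these differences stood out among the regroupings of the animals into 3 and 3 (2-sided exact permutation test, p = 0.7, 0.4, 0.8 and 0.6 in the order given, each 0.8 after Benjamini-Hochberg adjustment, where 0.1 is the smallest p that 3 against 3 animals allow).

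The share of elongating spermatid-like cells rested on stressed replicate 1. There it was 11.98% (Wilson 95% interval 9.18 to 15.5), against 69.0% (67.1 to 70.7) and 45.5% (43.4 to 47.5) in stressed replicates 2 and 3 and 50.3%, 55.7% and 49.3% in the controls. Without stressed replicate 1, the stressed mean lay 5.43 percentage points above the control mean, and with all libraries the difference was -9.64 points. In stressed replicate 1, 228 of the 409 cells, 55.7% (50.9 to 60.5), lay in the unnamed cluster led by Apoe, Fos and Cd74. Of the marker lists this cluster scored highest for elongating spermatids, with 14 supporting markers, and was left unnamed because its leading genes held more macrophage markers. Elongating spermatid markers summed to 149467 CPM in its cells in stressed replicate 1 and to 141726 ± 7240 CPM in the elongating spermatid-like cells of controls. That cluster held 61 cells of control replicate 2 (3.39%, 2.65 to 4.33), 3 of control replicate 1, 2 of stressed replicate 2 and 3 of stressed replicate 3. In control replicate 3 it held 0 of 2453 cells, which allows a share of up to 0.122%. With this cluster counted as elongating spermatid-like, a choice made after seeing the data, the difference was 7.84 points (exact permutation p = 0.4). The difference in spermatocyte-like share also turned without control replicate 1, from -1.32 to 2.85 points, and without stressed replicate 1 it was 1.04 points. The difference in spermatogonia-like share, 0.0676 points, became -0.0480 points without stressed replicate 1 and -0.00706 points without control replicate 3. Stressed replicate 1 gave 2 spermatogonia-like cells. A single cell held all 691 stromal marker counts of that class there, and a single cell 433 of the 439 immediate early gene counts, so the class is uncertain in this library. Among the 4 germ cell classes alone, round spermatid-like cells made up 35.8% ± 8.61 of control and 40.0% ± 18.8 of stressed cells (exact permutation p = 0.8), and elongating spermatid-like cells 52.4% ± 4.54 and 47.2% ± 21.0 (p = 0.7, same exact test).

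The clusters that made up a class differed between libraries. Cluster 11 held a mean of 47.5% of the spermatocyte-like cells in controls (1.17% to 87.0% per library) and 26.0% in stressed animals (0% to 58.3%), and cluster 13 held 28.9% (0% to 67.8%) and 42.5% (23.2% to 63.6%). In the round spermatid-like cells cluster 0 held 27.002% of control (0.179% to 47.6%) and 16.5% of stressed cells (1.85% to 34.5%), and cluster 10 held 18.03% (0.268% to 45.3%) and 25.5% (12.4% to 33.3%). In the elongating spermatid-like cells cluster 4 held 14.7% of control (10.4% to 18.7%) and 33.5% of stressed cells (9.16% to 77.6%, the highest in stressed replicate 1), and cluster 7 held 15.4% (0% to 32.6%) and 8.08% (2.04% to 11.5%).

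**Figure D1:**
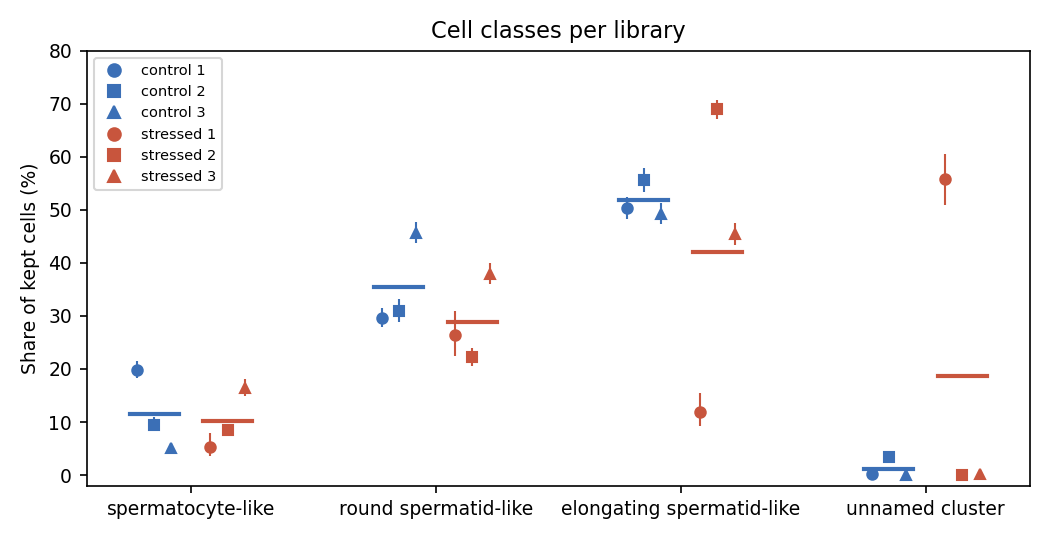
Share of kept cells (percent, vertical axis) in 3 germ cell classes and the unnamed cluster for each library, with controls in blue and stressed animals in red. Points are libraries, vertical bars Wilson 95% intervals and horizontal lines group means; stressed replicate 1 has 11.98% elongating spermatid-like cells and 55.7% of its cells in the unnamed cluster.

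In the round spermatid-like cells, 2 genes passed the test, both with identifiers in place of symbols and of unknown function here. AABR07001902.1 rose from 2.50 ± 0.934 CPM in controls to 29.7 ± 2.06 CPM in stressed animals (log2 change 3.55, SE 0.37, adjusted p = 0.0137 by edgeR with Benjamini-Hochberg adjustment), and ENSRNOG00000071151 fell from 29.3 ± 0.472 to 1.44 ± 0.576 CPM (log2 change -4.23, SE 0.37, adjusted p = 0.00617). Each group's 3 libraries lay apart from the other group's for both genes. Among genes with symbols that did not pass, Stx17, a membrane fusion protein of autophagosomes, was at 1.91 ± 0.398 CPM in controls and 8.63 ± 3.75 in stressed animals (log2 change 2.19, SE 0.46), and Pheta1, an adaptor of endosomal traffic, had 298 counts in controls and 2 in stressed animals (control over stressed ratio 75.5, counting interval 20.7 to 626). Their adjusted p were 0.998 and 0.388 by edgeR.

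Other round spermatid-like genes named by the rule were higher in the stressed libraries without passing. Tgs1, an RNA cap methyltransferase, had a log2 change of 3.401 (SE 0.79), and Cttnbp2 of 3.03 (SE 0.72). Exoc3l2 had 2 counts in controls and 33 in stressed animals, a ratio of 32.6 with a counting interval of 8.33 to 280. Lower were RT1-Bb, a chain of major histocompatibility complex class II (-2.68, SE 0.58), Ubb, which encodes ubiquitin (-1.096, SE 0.281), and Timm23, a subunit of the mitochondrial import channel (-1.39, SE 0.37). Btg3 had 93 counts in controls and 1 in stressed animals, a control over stressed ratio of 47.1 with a counting interval of 8.25 to 1880. All of these had an adjusted p of 0.998 by edgeR. RT1-Bb and Ubb belong to families of similar genes, so their counts may be shared with relatives. The groups did not overlap for 7.95% of the 12122 tested genes, where chance alone gives 10%, and 337 genes had an unadjusted p under 0.05. DESeq2 called 8 genes. With the replicate number as a block edgeR called 0. The edgeR count was also 0 without control replicate 1 and 0 without stressed replicate 2. AABR07001902.1 then had an adjusted p of 0.221 and 0.137, and 0.0752 without control replicate 2, and over all alternatives it ranged from 2.75e-20 to 0.221. For ENSRNOG00000071151 the values without control replicate 1 and without stressed replicate 2 were 0.130 and 0.0647, and the range was 1.09e-27 to 0.130.

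Genes of the spermatid programme did not pass the test in the round spermatid-like cells. The log2 change was 0.50 (SE 0.38) for Tnp1 and 0.40 (SE 0.23) for Tnp2, the transition proteins that replace histones, 0.39 (SE 0.26) for the protamine gene Prm2, 0.25 (SE 0.24) for Akap4 of the sperm tail and -0.13 (SE 0.30) for the acrosomal gene Acrv1, which was 0.13 without control replicate 2. Nr3c1, the glucocorticoid receptor, was at 3.10 ± 1.86 CPM in controls and 2.73 ± 1.73 in stressed animals (log2 change -0.10, SE 0.67, and 0.39 without control replicate 2). Each had an adjusted p of 0.998 by edgeR. The glucocorticoid targets Fkbp5 and Tsc22d3 were below the filter, with 18 and 5 counts in controls and 5 and 2 in stressed animals.

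In the elongating spermatid-like cells, AABR07001902.1 was the gene called, at 1.82 ± 0.617 CPM in controls and 22.9 ± 2.29 in stressed animals (log2 change 3.64, SE 0.40, adjusted p = 0.00500 by edgeR with Benjamini-Hochberg adjustment, higher in 3 of 3 stressed libraries). Genes with symbols did not pass. Pimreg, a mitotic regulator, was at 0.264 ± 0.0763 and 2.46 ± 1.05 CPM (log2 change 3.15, SE 0.69), Rassf4 at 0.467 ± 0.177 and 3.48 ± 2.04 CPM (2.80, SE 0.65), and Npm3, a histone chaperone, at 6.32 ± 3.74 and 20.6 ± 7.16 CPM (1.68, SE 0.47). Cttnbp2 (3.79, SE 0.92) and Slc6a18, an amino acid transporter gene (1.96, SE 0.49), were also higher. Faxc was at 4.89 ± 1.71 and 0.565 ± 0.494 CPM (-2.77, SE 0.63). The sialyltransferase gene St3gal4 had 63 counts in controls and 0 in stressed animals, at least 14.9-fold lower, from a floor of 3 counts over the group. RT1-DMb had 73 and 3 counts (control over stressed ratio 17.3, counting interval 5.68 to 85.6). Vps13c (-4.13, SE 1.12) and Faim, an inhibitor of Fas-driven apoptosis (-2.86, SE 0.91), were lower. Each of these had an adjusted p of 1.00 by edgeR.

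The abundant spermatid transcripts differed by less than the spread between animals in the elongating spermatid-like cells. Tnp1 was at 33378 ± 17213 CPM in controls and 29765 ± 7433 in stressed animals (log2 change -0.17, SE 0.43), Tnp2 at 17045 ± 2899 and 16172 ± 7262 (-0.08, SE 0.41) and Prm2 at 20427 ± 6792 and 18697 ± 10163 (-0.13, SE 0.47). Tnp1 turned to 0.32 without control replicate 2, and Tnp2 and Prm2 to 0.25 and 0.26 without stressed replicate 1. The log2 change was -0.31 (SE 0.33) for Akap4, 0.24 (SE 0.45) for Acrv1, which was -0.52 without stressed replicate 1, and 0.78 (SE 0.62) for Nr3c1. None passed, with an adjusted p of 1.00 each by edgeR. Fkbp5 had 33 and 26 counts and Tsc22d3 6 and 3, below the filter. Of 11039 genes, 174 had an unadjusted p under 0.05, and groups did not overlap for 6.40%, where chance gives 10%. DESeq2 called 5 genes. The edgeR count was 0 without control replicate 1, where AABR07001902.1 had an adjusted p of 0.0602, and 2 without control replicate 2, stressed replicate 2 or stressed replicate 3. Over all alternatives AABR07001902.1 ranged from 2.78e-17 to 0.0602.

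In the spermatocyte-like cells no gene passed: edgeR called 0 of 9858, with 193 at an unadjusted p under 0.05, and DESeq2 called 3. Kdm1a, a histone demethylase, was at 83.4 ± 8.17 CPM in controls and 160 ± 4.92 in stressed animals (log2 change 0.94, SE 0.26), Stx17 at 9.38 ± 0.919 and 26.8 ± 10.03 CPM (1.54, SE 0.46) and the proliferation marker Mki67 at 202 ± 29.7 and 346 ± 48.6 CPM (0.77, SE 0.24). Myo10 was also higher (1.104, SE 0.365). Pheta1 had 437 counts in controls and 5 in stressed animals (log2 change -5.70, SE 0.89). Gcsh, a protein of glycine breakdown, had 106 and 0 counts, at least 23.0-fold lower, from a floor of 3 counts over the group. The mitochondrial gene Mt-nd4l was at 330 ± 77.6 and 166 ± 27.9 CPM (-0.998, SE 0.270), and it overlaps a neighbouring mitochondrial gene, so its counts are uncertain. RT1-Bb (-2.29, SE 0.72) and Spata31a5 (-1.37, SE 0.44) were lower. The groups overlapped for RT1-Bb, at 63.9, 9.21 and 18.5 CPM in control replicates 1 to 3 and 9.41, 5.08 and 5.59 CPM in stressed replicates 1 to 3. Pheta1 had an adjusted p of 0.257 and each other gene 0.998 by edgeR.

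Stressed replicate 1 gave 22 spermatocyte-like cells and stood apart in some of these genes. Sparcl1, a matrix protein, was at 305 CPM there and at 4.93 to 11.4 CPM in the other 5 libraries. Markers of stromal cells summed to 893 CPM in its spermatocyte-like cells and to 1.67 to 24.7 CPM in the others, and markers of macrophages to 189 CPM against 40.5 to 64.5 CPM. A single cell held 672 of the 728 stromal marker counts there, and a single cell 242 of the 259 Sparcl1 counts. The synaptonemal complex gene Sycp3 had a log2 change of 0.23 (SE 0.35), the piRNA gene Piwil1 of 0.11 (SE 0.39) and Nr3c1 of -0.19 (SE 0.91), each with an adjusted p of 0.998 by edgeR. Without stressed replicate 1 they were -0.03, -0.26 and 0.24. Fkbp5 had 21 counts in controls and 3 in stressed animals, and Tsc22d3 5 and 26, both below the filter, with 24 of the 26 in a single cell. Groups did not overlap for 8.05% of genes, where chance gives 10%.

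Summed over all cells of a library, AABR07001902.1 was again the gene called, at 2.16 ± 0.775 CPM in controls and 29.5 ± 8.31 in stressed animals (log2 change 3.77, SE 0.42, adjusted p = 0.0202 by edgeR with Benjamini-Hochberg adjustment). Pheta1 came next, with 755 counts in controls and 8 in stressed animals (log2 change -5.85, SE 0.78, adjusted p = 0.0681 by edgeR, lower in 3 of 3 stressed libraries), and did not pass. Smox, a spermine oxidase (1.86, SE 0.46), Stx17 (1.90, SE 0.45), Cttnbp2 (2.79, SE 0.68), Unc79 (1.75, SE 0.48) and Mdga1 (1.07, SE 0.31) were higher, and Faxc (-2.38, SE 0.59), Gtf2h4, a subunit of a transcription and DNA repair complex (-3.34, SE 0.90), and the growth factor Pdgfa (-3.27, SE 0.95) were lower. Each of these had an adjusted p of 1.00 by edgeR. The groups overlapped for Gtf2h4, at 0.332 CPM in control replicate 3 and 0.199 to 0.574 CPM in the stressed libraries, and for Pdgfa, at 0.262 CPM in control replicate 1 and 0.133 to 0.482 CPM in the stressed libraries. Of 14519 genes, 200 had an unadjusted p under 0.05, and groups did not overlap for 4.91%, where chance gives 10%. DESeq2 called 3 genes. The edgeR count was 0 without control replicate 1, control replicate 3 or stressed replicate 2, 3 without stressed replicate 1 and 2 without stressed replicate 3. AABR07001902.1 had an adjusted p of 0.353, 0.157 and 0.144 in the fits with a count of 0 and of 0.0737 without control replicate 2, over a range of 1.68e-16 to 0.353. Pheta1 had 0.0471 without stressed replicate 1, over a range of 3.53e-09 to 0.824.

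**Figure D2:**
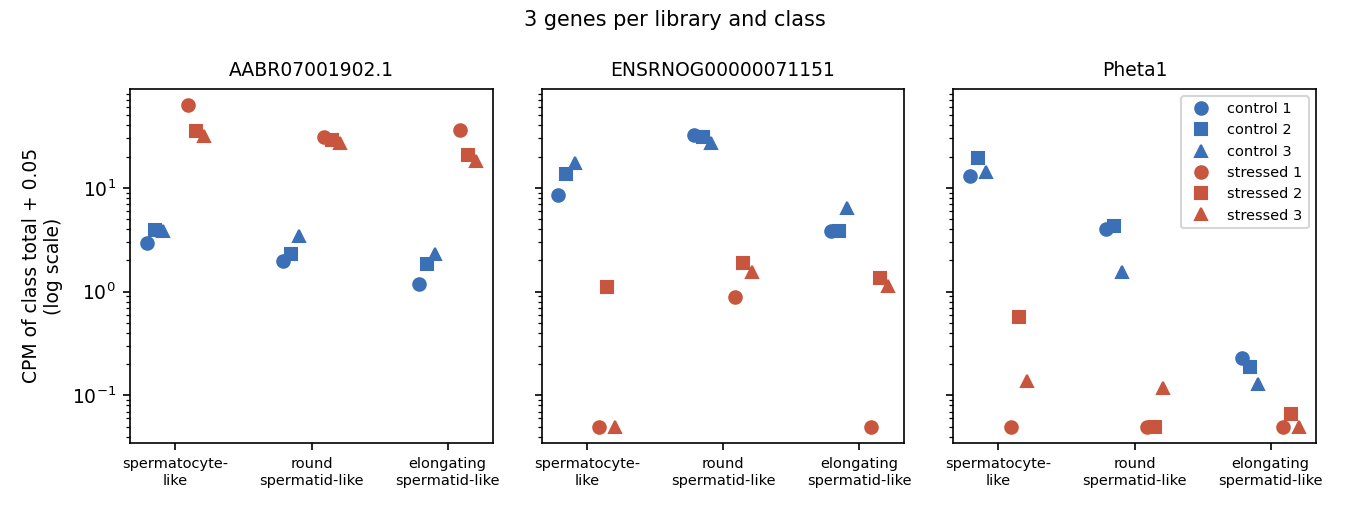
Level of 3 genes (CPM of the class total plus 0.05, log axis) in each library and germ cell class, with controls in blue and stressed animals in red and marker shapes for replicates. AABR07001902.1 is higher in each stressed library than in each control in all 3 classes, and ENSRNOG00000071151 is lower. Pheta1 is lower in the spermatocyte-like and round spermatid-like cells and passed the test in neither. In the elongating spermatid-like cells Pheta1 lay near the floor, with too few counts to be tested.

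Of the 75 tests of a fixed gene list in a class, 1 passed. Nuclear genes of oxidative phosphorylation, which encode the respiratory chain and ATP synthase, rose as a group in the spermatocyte-like cells (53 of 67 members higher, median log2 change 0.20, adjusted p = 0.00160 by camera in limma with Benjamini-Hochberg adjustment, n = 3 per group). The adjusted p = 0.898 with an estimated correlation, and 0.954 with fry. Its members with the smallest p were Cox8c (0.63, SE 0.35), Cox6a1 (0.40, SE 0.23), Ndufc1 (0.43, SE 0.26) and Ndufa1 (1.24, SE 0.77), and 0 members passed over all genes or adjusted over the list alone by edgeR, with 0 at an unadjusted p under 0.05. Ndufa1 was -0.28 without stressed replicate 1, where a single cell held 110 of its 125 counts. The list's adjusted p was 0.0950 without control replicate 1 and 0.0872 without stressed replicate 2, over a range of 7.4e-05 to 0.954. Camera called 6 lists without control replicate 2, 2 without control replicate 3 and 7 without stressed replicate 3. In the round spermatid-like cells 49 of 69 members were lower (median -0.08, adjusted p = 0.578 by camera), and in the elongating spermatid-like cells 34 were higher and 34 lower (adjusted p = 0.894 by camera). The difference between classes was not tested.

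Other lists did not pass, and their p depended on the test and on single libraries. Cytosolic ribosomal proteins had 52 of 66 members higher (median log2 change 0.19) and proteasome subunits 25 of 34 (median 0.10) in the spermatocyte-like cells, each with an adjusted p of 0.0851 by camera. Genes of ubiquitin ligases and deubiquitinases of spermatids had 17 of 21 members lower in the elongating spermatid-like cells (median -0.22, adjusted p = 0.0851) and 18 of 23 lower in the spermatocyte-like cells (median -0.29, adjusted p = 0.112, both by camera). Genes of the sperm tail and axoneme had 28 of 39 members lower in the spermatocyte-like cells (adjusted p = 0.143), and genes of chromatin condensation 13 of 17 higher in the round spermatid-like cells (adjusted p = 0.144, both by camera). With an estimated correlation each of these had an adjusted p of 0.898, and with fry 0.954. The ribosomal list had an adjusted p of 1.11e-06 without stressed replicate 3 and 1.35e-06 without control replicate 2, 0.806 without stressed replicate 1 and 0.0167 with the replicate number as a block. Each of the others also passed when a single library was left out, either control replicate 2 or stressed replicate 3. With the block the proteasome list (0.0367), both tests of the ubiquitin list (0.0167 in the elongating spermatid-like and 0.0265 in the spermatocyte-like cells) and the sperm tail list (0.0104) also passed.

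Lists that bear on a stress response did not pass with all libraries and no block. The glucocorticoid response list had 6 of 7 members higher in the round spermatid-like cells (median log2 change 0.29, adjusted p = 0.578 by camera) and 4 of 7 in the elongating spermatid-like cells (0.07, adjusted p = 0.831), and too few tested members in the spermatocyte-like cells. The immediate early genes had 9 of 12 members higher in the round spermatid-like cells (0.49, adjusted p = 0.831) and 7 of 14 in the elongating spermatid-like cells (-0.01, adjusted p = 0.803, both by camera). The unfolded protein response had 12 of 14 members higher in the spermatocyte-like cells (0.23, adjusted p = 0.160, and 0.0445 without stressed replicate 2), and heat shock genes 11 of 17 (0.15, adjusted p = 0.967, both by camera), a list whose test pointed down. Genes of oxidative stress defence had 15 of 18 members higher in the spermatocyte-like cells (adjusted p = 0.497 by camera, and 0.0101 with the replicate number as a block). Meiosis and synapsis genes had 13 of 25 members higher in the spermatocyte-like cells (0.05, adjusted p = 0.587 by camera), again with the test pointing down. Over all lists, the median had another sign than the test in 24 of the 75 tests and the mean in 19. Over the lists, 0 members passed over all genes and 3 when adjusted over the list alone, with 9 list tests at an unadjusted p under 0.05.

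Immediate early genes and macrophage genes were high in stressed replicate 1 alone. In the whole-library sums, the immediate early genes summed to 215 CPM there, against 65.0, 94.8 and 59.0 CPM in the controls and 63.5 and 58.4 CPM in stressed replicates 2 and 3. Macrophage markers summed to 155 CPM, against 35.7 to 47.0 CPM in controls and 24.5 and 45.6 CPM in the other stressed libraries. Stromal markers summed to 142 CPM there and to 16.6 CPM in control replicate 2, with 2.23 to 3.55 CPM in the other 4 libraries. In stressed replicate 1, 2 cells held 1363 of the 2378 stromal counts, and without them the sum was 60.6 CPM. Differences in group means of these lists did not stand out among the regroupings of the animals (2-sided exact permutation test, p = 0.9, 0.8 and 0.6, smallest possible 0.1).

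**Figure D3:**
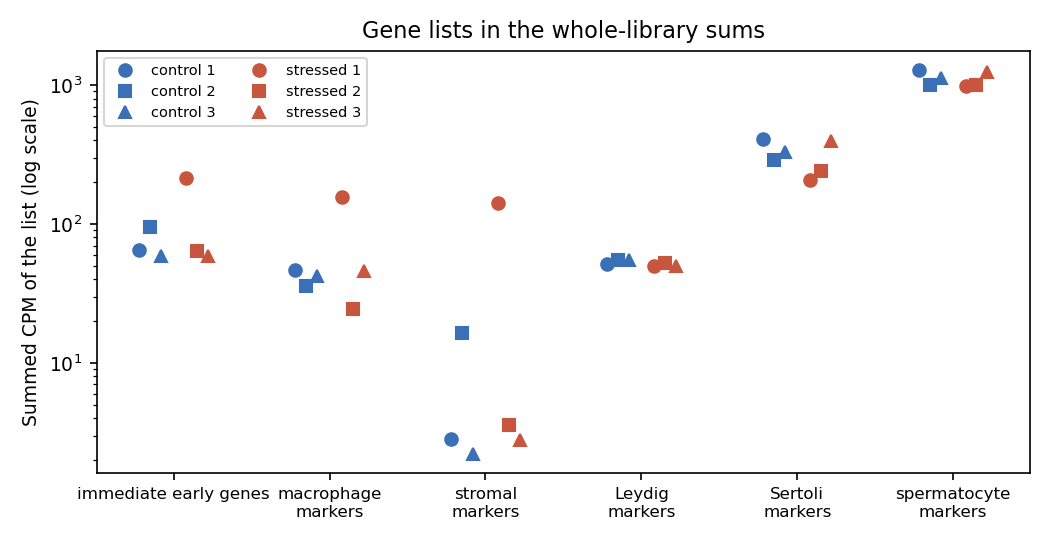
Summed CPM (log axis) of 6 fixed lists in the whole-library sums of each library, with controls in blue and stressed animals in red and marker shapes for replicates. Stressed replicate 1 stands above the other libraries for immediate early genes (215 CPM), macrophage markers (155 CPM) and stromal markers (142 CPM).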

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

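The tests of doublets, of a response shared by the stressed animals and of a lower limit on genes per cell were chosen only after the result was seen, as were the ratios of control libraries and of single clusters set beside them, and the other tests of an explanation were fixed before their result was seen.

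In stressed replicate 1, 55.7% of the cells lay in the unnamed cluster, which enters no class comparison and held at most 3.39% of the cells of a control library. The cluster and the high immediate early and macrophage RNA of that library were weighed together. In immediate early genes, 1 of the 3 stressed libraries lay above the highest control, so their sum was not raised in every stressed animal. That restates the pattern that prompted the test, so it is no separate evidence on a response shared by the stressed animals. Doublets of a germ cell and a whole macrophage stay open as the source of the cluster. Of its 228 cells in that library, 0 (Wilson 95% upper bound 1.66%) held counts of at least 7 of the 14 macrophage markers. The highest number in a cell was 6, and 31 cells held none. No macrophage cluster was found to show how many of these markers a macrophage would hold here, so the bound of 7 cannot decide. A first test of doublets by total count also decided nothing. The unnamed cells held 1.02 times the median total count of the elongating spermatid-like cells of that library, but 38 of those 49 cells lay in cluster 4, and against the medians of single elongating spermatid-like clusters over all libraries the ratio ran from 0.887 to 1.505, so the outcome depends on the reference cells. Free RNA of a single source stays open. The ratio of immediate early to macrophage counts differed 4.29-fold between the parts of the library, past the bound set beforehand, but in the controls, which lack the pattern, it differed 11.9-fold, 4.74-fold and 8.44-fold between the germ cell classes, so the bound was wrong and the spread decides nothing. Several sources of free RNA, and something particular to this animal or its dissociation, were not tested and stay open.

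AABR07001902.1 separated the groups by large folds in all 3 germ cell classes, with a log2 change of 3.55 to 3.65. The other called gene, ENSRNOG00000071151, had uneven log2 changes of -4.78 (SE 1.15), -4.23 (SE 0.37) and -2.17 (SE 0.62) in the spermatocyte-like, round and elongating spermatid-like cells. A difference in depth is argued against for AABR07001902.1 by libraries of near-equal depth. Control replicate 1 and stressed replicate 2 held 94130353 and 93898869 counts, with 1.44 and 27.5 CPM in the whole-library sums. Control replicate 2 and stressed replicate 3 held 73650164 and 74453303 counts, with 2.07 and 22.4 CPM. After thinning to the shallowest library the lowest stressed count was still 8.59 times the highest control count. Thinning keeps CPM ratios on average, so that value largely repeats the gap. A genotype that differs between the animals may give such gaps, but it cannot be told apart from an effect of stress, because with 3 animals per group every stressed animal could share a variant. Among 8384 genes, 1 lay at least 4-fold apart in all 3 classes in the real split, and 0 of the other splits had as many, with 0 as their highest value. An effect of the stress itself stays open and untested.

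Clusters of the 3 germ cell classes were near-missing together from some libraries. Clusters 0, 5, 6 and 11 held 1.17% of the spermatocyte-like, 0.179% of the round spermatid-like and 0.0997% of the elongating spermatid-like cells of control replicate 2, against 54.4%, 33.2% and 30.03% in control replicate 1. They were also scarce in stressed replicate 1, with 0 of 22, 2 of 108 and 3 of 49 cells of these classes, so the gap also enters the comparison of the groups. A lower limit on genes per cell is argued against for this gap, since 1.31% of the control replicate 1 cells in these clusters held fewer genes than any cell of control replicate 2, and 0.119% fewer than any cell of stressed replicate 1. Clusters 7, 10, 12 and 13 were in turn near-missing from control replicate 3, with 0 of 123, 3 of 1120 and 4 of 1209 cells of the classes. An upper limit as the only source is argued against for that gap over the classes together. Of the control replicate 1 cells in these clusters, 13.4% held more genes than any cell of control replicate 3. The share was not taken per class. In the spermatocyte-like cells of cluster 13 a limit may add to the gap, as their median of 3522 genes lay near the highest cell of control replicate 3, at 3559. These tests speak to a fixed limit only, as genes per cell did differ between the sets. In the spermatocyte-like cells of control replicate 1, the median was 2175.5 genes in cluster 11 and 3522 in cluster 13. Over all libraries the median was 2089, 1188, 1034 and 2096 in clusters 0, 5, 6 and 11. It was 1706, 3116, 1823 and 3192 in clusters 7, 10, 12 and 13. A difference in RNA quality or handling may be involved, since within control replicate 1 the changes between both sets of clusters correlated across genes between classes with r of 0.447 to 0.522, but the lowest lay between the bounds set beforehand, and genes are not independent replicates. No biological explanation was tested, as the design gives none.

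With 6 samples, the 10 splits into 3 and 3 are too few for a share under 0.05. In the spermatocyte-like cells edgeR called 0 genes in the real split and at most 0 in the others, with 193 at an unadjusted p under 0.05 and 3 calls by DESeq2 in the real split, so 10 of the 10 splits had as many. For the round spermatid-like cells the real count was 2, the highest other 7, and 3 splits had as many. For the elongating spermatid-like cells the values were 1, 2 and 5, for the whole-library sums 1, 2 and 6, and for the gene lists 1, 10 and 9. The split of control replicates 1 and 3 and stressed replicate 3 against the rest gave 2909 genes at an unadjusted p under 0.05 in the whole-library sums, where the real split gave 200, which points to a structure of the samples that does not follow the groups.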

How the results depend on the processing

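Leaving out control replicate 2 and stressed replicate 1 together and both ways of treating the unnamed cluster were chosen only after the data were seen. Tests planned for cell types without a cluster, and shares among somatic classes, were not run. Of 122 alternative values of counts and shares, 84 kept their direction and size class, 30 moved and 8 reversed. Of 63 named genes by class, 52 never changed direction. Most of the 63 were picked by their p in these same data, which favours a steady direction, so the count does not measure robustness. The genes that did turn were all fixed or list genes, given below. Where no cause is named, the cause was not tested. Changes of a count by a few genes rest on few calls, and stressed replicate 1, with 16756543 counts, limits each comparison.

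DESeq2 called 3 genes in the spermatocyte-like sums (edgeR 0, with 193 at an unadjusted p under 0.05), 8 in the round spermatid-like sums (edgeR 2), 5 in the elongating spermatid-like sums (edgeR 1) and 3 in the whole-library sums (edgeR 1). Without a filter on low counts, which adds genes to the test, edgeR called 2, 3, 9 and 2. limma voom called 1 gene in the spermatocyte-like sums. With control replicate 2 and stressed replicate 1 left out, edgeR called 9 genes in the round spermatid-like, 2 in the elongating spermatid-like and 11 in the whole-library sums, and camera 4 lists. Leaving out each replicate in turn, edgeR counts ran from 0 (without control replicate 1) to 3 (without control replicate 2) in the round spermatid-like sums, from 0 (without control replicate 1) to 2 (without control replicate 2, stressed replicate 2 or stressed replicate 3) in the elongating spermatid-like sums, and from 0 (without control replicate 1) to 3 (without stressed replicate 1) in the whole-library sums. In the spermatocyte-like sums they stayed at 0, with 142 to 520 genes at an unadjusted p under 0.05. Counts of 0 came with 118 to 450 genes at an unadjusted p under 0.05 in the round spermatid-like, elongating spermatid-like and whole-library sums. Camera called 1 to 7 lists (lowest without control replicate 1, highest without stressed replicate 3), and 0 with an estimated correlation and 0 with fry, where 2 tests each had an unadjusted p under 0.05.

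With the replicate number as a block, edgeR called 0 genes in the round spermatid-like sums (229 at an unadjusted p under 0.05) and camera 8 lists, and the counts of 0, 1 and 1 in the spermatocyte-like, elongating spermatid-like and whole-library sums were as without it. The labels do not say whether the numbers pair the animals. Deviations of same-numbered libraries correlated at -0.139 to 0.242, with 9 of 12 values under 0.1, and 7 of 18 samples by class correlated best with their own number. For number 3 the values were 0.0399 to 0.242, and for numbers 1 and 2 -0.139 to 0.0660. Such values give little sign of pairing, but with 3 libraries per group they cannot exclude it.

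The difference in elongating spermatid-like share, -9.64 points, became 10.1 points with clusters found within each library, 7.84 points with the unnamed cluster counted in, and ran from -23.1 points (without stressed replicate 2) to 5.43 points (without stressed replicate 1). The spermatocyte-like difference, -1.32 points, became 2.60 points with clusters found within each library and ran from -4.53 points (without control replicate 3) to 2.85 points (without control replicate 1). Clustered alone, control replicate 3 had no cluster named spermatocyte-like, against 5.01% of its cells in the main clustering. Its cluster of 447 cells led by mitochondrial genes was named round spermatid-like. In control replicate 2, a cluster of 61 cells with spermatocyte markers among its leading genes stayed unnamed. The spermatocyte-like and round spermatid-like differences of that alternative thus depend on the naming of single clusters. The round spermatid-like difference, -6.58 points, became -11.6 points with clusters found within each library and ran from -11.1 points (without stressed replicate 3) to -1.47 points (without control replicate 3). The spermatogonia-like difference ran from -0.0480 points (without stressed replicate 1) to 0.195 points (without control replicate 2).

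Fixed and list genes, none of which passed, reversed in log2 change as follows. In the spermatocyte-like sums with at least 50 cells per library, which leaves out stressed replicate 1, Nr3c1 was 0.24, Sycp3 -0.032, Piwil1 -0.26 and Ndufa1 -0.28, and with both doubted libraries left out Nr3c1 was 0.29, Piwil1 -0.082 and Ndufa1 -0.065. Piwil1 was -0.23 with limma voom. In the round spermatid-like sums Nr3c1 was 0.26 with limma voom and 0.77 with both left out. In the elongating spermatid-like sums with at least 50 cells Tnp1 was 0.0097, Tnp2 0.25, Prm2 0.26 and Acrv1 -0.52. With both left out Tnp1 was 0.50, Tnp2 0.13, Prm2 0.038, Akap4 0.093 and Acrv1 -0.54. With limma voom Tnp2 was 0.050, Prm2 0.034 and Acrv1 -0.39. With clusters found within each library Tnp2 was 0.13, Prm2 0.0033 and Acrv1 -0.079. With the unnamed cluster counted in Tnp1 was 0.063, Tnp2 0.24, Prm2 0.11, Akap4 0.065 and Acrv1 -0.50.

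Leaving out each replicate, the spermatocyte-like log2 changes ran from -1.17 to 0.24 for Nr3c1, -0.032 to 0.52 for Sycp3, -0.26 to 0.48 for Piwil1 and -0.28 to 1.83 for Ndufa1. The round spermatid-like changes ran from -0.53 to 0.39 for Nr3c1 and -0.44 to 0.13 for Acrv1. The elongating spermatid-like changes ran from -0.44 to 0.32 for Tnp1, -0.32 to 0.25 for Tnp2, -0.43 to 0.26 for Prm2 and -0.52 to 0.53 for Acrv1.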

Other observations

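Genes of the somatic marker lists had counts in the libraries although no somatic cluster was found, and these counts need not come from somatic cells. In the whole-library sums, Leydig cell markers summed to 54.0 ± 2.07 CPM in controls and 50.8 ± 1.47 in stressed animals, and Sertoli cell markers to 342 ± 60.3 and 281 ± 99.3 CPM (2-sided exact permutation test, p = 0.2 and 0.4, n = 3 per group). Both lists hold genes that the germ cell classes also showed: Sertoli markers summed to 878 ± 65.5 CPM in the spermatocyte-like cells of controls. Erythroid markers summed to 4.85 ± 0.396 CPM in controls and 8.66 ± 2.54 CPM in stressed animals, higher in 3 of 3 stressed libraries than in the highest control (exact permutation p = 0.1, the smallest possible). Cell cycle genes summed to 2235 ± 261 CPM in controls and 2559 ± 76.0 in stressed animals in the spermatocyte-like cells, and to 239 ± 11.5 and 278 ± 22.5 CPM in the elongating spermatid-like cells, higher in 3 of 3 stressed libraries in both (exact permutation p = 0.1 each). In the round spermatid-like cells and the whole-library sums they were slightly lower in stressed animals, at 775 ± 36.2 and 761 ± 61.9 CPM and at 666 ± 139 and 627 ± 158 CPM (p = 0.8 and 0.7, same exact test), and in the elongating spermatid-like cells the camera test pointed down. Lower in 3 of 3 stressed libraries than in the lowest control, with an exact permutation p of 0.1 each, were the sums of sperm tail genes in the spermatocyte-like cells (17586 ± 236 and 15388 ± 1598 CPM), of Sertoli function genes (971 ± 54.8 and 793 ± 97.6 CPM) and piRNA pathway genes (4556 ± 134 and 4003 ± 403 CPM) in the round spermatid-like cells, and of spermatogonial self-renewal genes in the elongating spermatid-like cells (13.9 ± 0.494 and 12.6 ± 0.731 CPM), controls first. These were the 7 with the smallest possible p among 164 comparisons of summed lists. Chance alone gives that p in 10% of comparisons, so 7 is no excess over chance. With a smallest p of 0.1 none can pass an adjustment.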
